A study of Arabidopsis thaliana with 38 samples.

How the data were processed

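Rosettes of 25-day-old Arabidopsis thaliana plants of the Col-0 accession were profiled on Affymetrix ATH1 arrays, 1 array per RNA sample. The 38 samples fall into 16 groups by genotype, condition and RNA pool, which were taken from the sample titles. HF-RPL18 is the line 35S:HF-RPL18, which expresses a tagged ribosomal protein and served as the reference. CSP1-FH is the line 35S:AtCSP1-FH#11, which expresses a tagged cold shock protein CSP1, and atcsp1-1 is a mutant of that gene. HF-RPL18 has 18 arrays with 3 per group, CSP1-FH has 12 arrays with 2 per group, and atcsp1-1 has 8 arrays with 2 per group and no CSP1-IP arrays analysed here. The series design text calls the replicates biological.

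Per the labels' protocols, cold-treated plants spent 12 h in a chamber at 4 °C that also had lower light, and non-stress plants stayed at 23 °C. Cold began 2 h after the start of the light period. Polysomal RNA was the RNA with at least 2 ribosomes per mRNA from sucrose gradients, per the labels' protocols. For the CSP1 immunopurification (CSP1-IP), leaves were washed, cross-linked with formaldehyde under vacuum and ground, and RNA was recovered from antibody-coated Protein A beads, per the labels' protocols. The labels' protocols give an RNA amount for CSP1-IP labelling and another, without a unit, for the other pools. The amplified RNA was labelled with biotin by 3′ in vitro transcription, per the labels' protocols.

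The deposited values are log2 expression values per probe set, made by the authors with RMA (background correction, quantile normalisation and probe-set summary), per the submitters' processing notes. The version of RMA, and which arrays were normalised together, are not given in the sources used here. The deposited values were used without further normalisation. Array medians lay between 4.24 and 4.52, and the SD over probe sets was 2.22 to 2.32 on total and polysomal arrays but 1.83 to 2.14 on CSP1-IP arrays. No array column repeated another. For arrays there is no sequencing depth, so the number of arrays per group limits the precision.

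Of 22810 probe sets, 64 control probe sets were left out and 22746 were tested. The annotation table gave 1 gene for 13513 of the tested probe sets (59.4%), several genes for 503 and no entry for 8730. A probe set without an entry is unnamed here and keeps its probe-set ID, and no gene is named from a probe set with several genes. The annotation gave 145 genes more than 1 probe set, none of them a list member. CSP1, CSP2, CSP3, CSP4 and RPL18B had no named probe set, so the targeted gene was not checked by name in any sample.

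Tests were run in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), with a mean per group over all 38 arrays, a spread shared by the groups (22 residual and 5.22 prior degrees of freedom) and 2-sided p-values with Benjamini-Hochberg adjustment over all tested probe sets. Probe sets were called at an adjusted p below 0.05. Differences of differences were contrasts in the same model. Gene lists were tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation. Member calls were adjusted over all probe sets and over the list alone. In CSP1-IP comparisons, list medians were also set against 10000 random lists of the same size matched on mean level in 20 bins.

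The following lists were fixed before the data were examined: CBF regulon and cold acclimation, abscisic acid response, flavonoid and anthocyanin synthesis, nuclear photosynthesis genes, circadian clock, starch breakdown and raffinose synthesis, heat shock proteins and chaperones, jasmonate and wounding, salicylic acid and pathogen response, translation factors, cell division, guard cell, phloem, trichome and inflorescence markers, nuclear-encoded plastid ribosomal proteins, cytosolic ribosomal proteins, plastid-encoded genes and mitochondrion-encoded genes. Of these, 6 lists had 0 members with a named probe set and gave no result: abscisic acid response, starch breakdown and raffinose synthesis, salicylic acid and pathogen response, cell division, phloem markers, and inflorescence and floral organ markers. Another 7 lists were chosen after the names in the annotation had been seen: expansins and xyloglucan hydrolases, UDP-glycosyltransferases, late embryogenesis and dehydration genes, tubulins, SWEET sugar transporters, early stress and wound-inducible genes, and further nuclear chloroplast genes. The gene STZ is in both the CBF list and the early stress list.

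Genes were named by a rule fixed before the data were examined. It draws only on probe sets with 1 gene in the annotation. In each comparison it takes the 5 largest rises and the 5 largest falls with an adjusted p below 0.05 and no overlap between the arrays of the groups compared. For a difference of differences the condition on overlap was dropped. From each list it takes up to 4 members with the largest differences that passed, or the 2 with the smallest p where none passed. The set of mRNAs enriched in CSP1-IP was defined on CSP1-FH arrays as probe sets with an adjusted p below 0.05 and a log2 difference from total RNA of at least 1.

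The design, the tests and the alternatives were written before the data were examined, except for those named in the closing section as chosen later. The alternatives were a block for replicate number, a dim filter at the 30th percentile (log2 3.30), array weights, a trended and robust prior, a fit on the compared groups alone, polysomal RNA as the reference, and leaving out each array in turn. Added later were a fit without the CSP1-IP arrays, loess normalisation of every array (for gene lists also with an estimated correlation), matched lists in the CSP1-IP comparisons, and a fit without HF-RPL18 CSP1-IP cold arrays 1 and 3. Sequence features of the mRNAs were not analysed here.

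Replicate numbers come from the sample titles. Within HF-RPL18, total and polysomal arrays with the same number deviated together from their group means, with a correlation across probe sets of 0.49 to 0.73 in the same condition and 0.19 to 0.39 between conditions. For arrays of the same pool in both conditions it was 0.31 to 0.50. Every one of these pairs was above 0.1, so the numbers pair total and polysomal arrays of HF-RPL18. Pairs with a CSP1-IP array of that line gave −0.11 to 0.23 and were not taken as paired. The other lines have 2 numbers each, too few for that check.

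The steps were tested on simulated data with 200 of 22746 probe sets changed. In the total RNA cold comparison of 3 against 3 arrays, 0, 94 and 197 of 200 were recovered at log2 changes of 0.5, 1 and 2. In the comparison of atcsp1-1 with HF-RPL18, 0, 49 and 192 were recovered. False calls numbered 0, 0 and 1 in the first comparison and 0, 0 and 3 in the second. More false calls came in CSP1-IP against total RNA in non-stress. In CSP1-FH 61 and 183 were recovered at log2 1 and 2, with 15 and 25 false calls. In HF-RPL18 102 and 196 were recovered, with 3 and 17 false calls. The simulated noise was independent between arrays and between probe sets. It left out the shared deviations of same-numbered arrays and the correlation between genes, so counts in the data may differ.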

Results

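The series was designed to follow the cold-regulated transcriptome and translatome of Arabidopsis rosettes and the mRNAs associated with CSP1, a nucleic-acid-binding protein with a cold shock domain. Total RNA (14 arrays), polysomal RNA (14 arrays) and RNA recovered by CSP1 immunopurification (CSP1-IP, 10 arrays) were measured on 38 arrays from 3 lines, each kept at 23 °C (non-stress) or held at 4 °C for 12 h (cold). HF-RPL18, which carries a tagged ribosomal protein, had 3 arrays per group. CSP1-FH, which carries a tagged CSP1, and the mutant atcsp1-1 had 2 arrays per group. All values are RMA log2 values, differences are log2 differences with their SE from limma, and adjusted p-values are from limma or its camera test. Genes named as the largest rises and falls between groups had no overlap between the arrays compared. They were ranked only among probe sets with 1 gene in the annotation (59.4% of those tested), so unnamed probe sets may have larger differences. With 3 against 3 arrays, chance alone gives no overlap for 10% of probe sets, and the number of arrays limits the precision throughout.

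Cold acclimation genes rose in total RNA of HF-RPL18 in the cold. The dehydrin gene LTI30 had the largest rise, by 8.11 (SE 0.45, adjusted p = 5.31e-13), 276-fold, from 4.51 ± 0.56 to 12.62 ± 0.21 (mean ± SD, n = 3 in each group). The dehydrin gene COR47 rose by 4.57 (SE 0.30, adjusted p = 1.23e-11), from 8.70 ± 0.46 to 13.28 ± 0.10. COR15A, which encodes a cryoprotective chloroplast protein, rose by 2.21 (SE 0.51, adjusted p = 0.00344), and the zinc finger gene STZ rose by 2.51 (adjusted p = 0.0037). All 5 measured members of the CBF regulon list of 23 rose, and the same 5 passed when adjusted over the list alone. The list median was 2.51 (camera adjusted p = 7.8e-13, and adjusted p = 1.1e-06 with an estimated correlation).

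Other large rises in the cold were those of AT5G62360 (5.59), AT5G20790 (5.38), AT3G15450 (5.36) and AT5G62280 (5.22). The clock gene GI rose by 4.87 (SE 0.88, adjusted p = 0.00029), from 4.41 ± 1.64 to 9.28 ± 0.06. Its non-stress value was 6.30 on array 2 and 3.41 and 3.53 on the others. GI was the only measured member of the circadian list. The largest falls were those of TBL26, a member of the trichome birefringence-like family (−4.46, SE 0.70, adjusted p = 4.98e-05), AT2G34620 (−3.88), AT5G02230 (−3.65), AT1G23205 (−3.38) and AT1G68600 (−3.26). The ribosomal protein gene AT5G59240 rose by 1.31 (adjusted p = 0.000748) and AT5G39850 fell by 1.04 (adjusted p = 0.0283). Those were the only passing members among 120 measured cytosolic ribosomal protein genes, and 1 rose and 0 fell when adjusted over the list alone. The median of that list was 0.13 (camera adjusted p = 0.11, and adjusted p = 0.96 with an estimated correlation), and it passed after loess normalisation at 0.21 (camera adjusted p = 0.00583, but adjusted p = 0.926 with an estimated correlation).

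Of the remaining fixed lists, no plastid-encoded or mitochondrion-encoded gene and no nuclear gene of plastid ribosomal proteins passed in the cold response of total RNA. Of 7 nuclear photosynthesis genes LHCB4.2 rose, also when adjusted over the list alone (0.89, adjusted p = 0.0326). That call was lost without total non-stress array 1 (0.58, adjusted p = 0.266) or 3 (0.97, adjusted p = 0.0551) or total cold array 1 (0.93, adjusted p = 0.0712), 2 (0.81, adjusted p = 0.135) or 3 (0.94, adjusted p = 0.0597). None of the 4 measured flavonoid genes passed (DFR −1.34, adjusted p = 0.521), and the jasmonate marker PDF1.2 was at 0.78 (adjusted p = 0.675). None of the 3 translation factor genes passed (EIF4A-2 0.48, adjusted p = 0.322), and neither did the heat shock genes AT1G53540 (0.21, adjusted p = 0.873) and ATHSP22.0 (−0.03, adjusted p = 0.998). The guard cell marker AT1G22690 rose by 1.32 (adjusted p = 0.00169). The trichome marker TRY fell by 2.23 (adjusted p = 0.0166), a call lost without total cold array 1 (−2.18, adjusted p = 0.0567) or total non-stress array 3 (−1.73, adjusted p = 0.136). In all, limma called 2447 probe sets, 1210 higher and 1237 lower in the cold. The count was 3970 without the CSP1-IP arrays and 4806 with array weights. Cold plants also stood in lower light, so the responses to light and to temperature were not separated.

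LTI30 and TBL26 again had the largest rise and the largest fall in the cold response of polysomal RNA, the RNA loaded with ribosomes, in HF-RPL18. LTI30 rose by 7.10 (adjusted p = 1.11e-11), from 5.61 ± 0.52 to 12.71 ± 0.36 (n = 3 in each group), COR47 rose by 4.07 (adjusted p = 1.8e-10) and COR15B rose by 1.44 (adjusted p = 0.00274). Of the 5 CBF regulon genes measured, 4 rose, and 5 did when adjusted over the list alone. The list median was 2.24 (adjusted p = 5.2e-06 with an estimated correlation). The largest falls were those of TBL26 (−4.43), AT5G02230 (−3.71) and AT1G23205 (−3.55), while AT5G62360 rose by 5.21 and GI by 4.53. Among 69 plastid-encoded genes, the ribosomal protein gene rpl33 was lower (−1.29, adjusted p = 0.0126), a call lost without polysomal cold array 3 (−1.19, adjusted p = 0.0561) or polysomal non-stress array 1 (−1.16, adjusted p = 0.0644). It was also the only member to pass when adjusted over the list alone. The plastid-encoded list had a median of −0.44 (camera adjusted p = 0.0022, but adjusted p = 0.87 with an estimated correlation).

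In polysomal RNA limma called 2061 probe sets, 957 higher and 1104 lower. Of the calls in total RNA, 843 higher and 861 lower ones were shared with polysomal RNA, against 50.9 and 60.0 expected for independent lists, and 0 were opposite. Here and below, such lists are not independent, since same-numbered arrays deviated together, so the expected counts are a low baseline. The polysomal count was 3680 without the CSP1-IP arrays and 3565 with array weights.

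**Figure D1:**
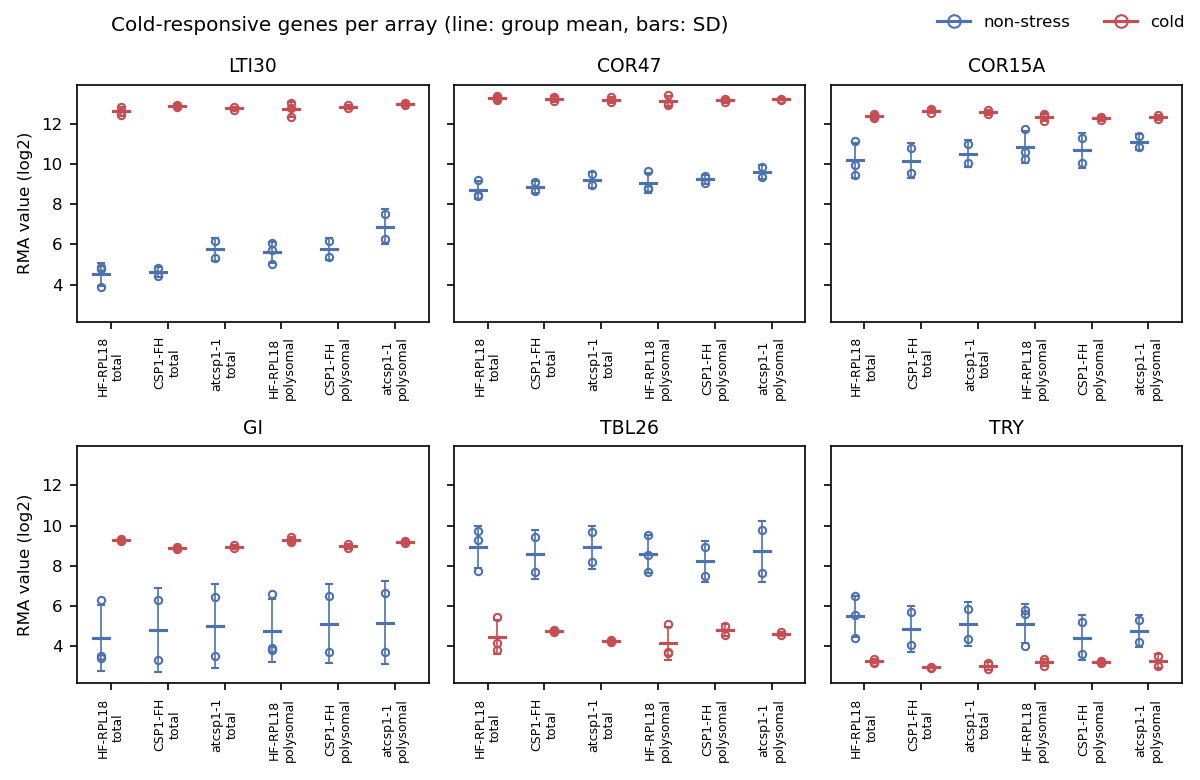
RMA values (log2) of 6 genes on each total and polysomal array of the 3 lines, in non-stress (blue) and cold (red). Points are arrays, lines are group means and bars are SDs. LTI30, COR47, COR15A and GI were higher and TBL26 and TRY lower in cold in HF-RPL18 total RNA, where LTI30 moved from 4.51 ± 0.56 to 12.62 ± 0.21.

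LTI30 had the largest rise and TBL26 the largest fall in total and polysomal RNA of both other lines in the cold. LTI30 rose by 7.01 (SE 0.55, adjusted p = 1.47e-09) in total RNA of atcsp1-1 and by 8.27 (SE 0.55, adjusted p = 3.94e-11) in that of CSP1-FH (n = 2 in each group). All 5 CBF regulon genes measured rose in total RNA of both lines, also when adjusted over the list alone, with medians of 3.31 in atcsp1-1 and 3.36 in CSP1-FH. Total RNA of atcsp1-1 gave 1627 calls, of which 710 higher and 696 lower ones were shared with HF-RPL18 (43.7 and 43.8 expected for independent lists). Total RNA of CSP1-FH gave 1295 calls, of which 675 higher and 521 lower ones were shared (38.4 and 31.2 expected). In polysomal RNA the counts were 1429 for atcsp1-1 and 1042 for CSP1-FH. These lines had fewer arrays than HF-RPL18, and the difference in counts was not tested.

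Polysomal RNA was compared with total RNA to see which mRNAs were over- or under-represented on polysomes. In non-stress HF-RPL18 the largest excess on polysomes was that of AT3G53950 (1.54, SE 0.35, adjusted p = 0.0241), with 7.47 ± 0.68 against 5.92 ± 0.11 (n = 3 in each group), followed by AT1G07750 (1.53), AT1G21670 (1.49) and AT5G42720 (1.44). The largest deficit was that of AT1G65370 (−2.21, SE 0.41, adjusted p = 0.00826), at 3.26 ± 0.22 against 5.47 ± 0.47, followed by AT1G02300 (−1.89), AT3G53670 (−1.71) and AT2G01100 (−1.69). The polysomal mean of AT1G65370 lay below the dim-filter level of log2 3.30, so the size of its deficit is uncertain. Among 120 cytosolic ribosomal protein genes and 69 plastid-encoded genes none passed, also when adjusted over the list alone. The ribosomal protein list had a median of 0.18 (camera adjusted p = 0.00064, but adjusted p = 0.72 with an estimated correlation), and −0.01 without polysomal array 1. The plastid-encoded list had a median of −0.33 (camera adjusted p = 0.00059, but adjusted p = 0.72 with an estimated correlation), and −0.06 without polysomal array 2.

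In all, 254 probe sets differed between polysomal and total RNA in non-stress, 63 higher and 191 lower on polysomes. With the replicate number as a block, which pairs these arrays, the count was 500. It was 1363 without the CSP1-IP arrays, 1217 with array weights and 95 with the compared groups alone. Leaving out an array gave 27 (total array 3), 54 (polysomal array 3), 91 (total array 2), 105 (polysomal array 1) or 153 (total array 1). The call of AT3G53950 was lost without polysomal array 3 (1.15, adjusted p = 0.219) or without total array 1 (adjusted p = 0.072), 2 (adjusted p = 0.0867) or 3 (adjusted p = 0.0792).

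In cold HF-RPL18 AT5G28430 had the largest excess on polysomes (2.02, SE 0.30, adjusted p = 0.000897), with 7.46 ± 0.09 against 5.45 ± 0.53 (n = 3 in each group). Then came AT1G72230 (1.48), AT3G14067 (1.47) and AT1G07750 (1.42). Lower on polysomes were AT5G47435 (−2.26, adjusted p = 0.000246), AT5G57655 (−2.17) and AT5G66060 (−1.99). Of the 69 plastid-encoded genes 7 were lower on polysomes, and 9 were when adjusted over the list alone. Among these were psbE of photosystem II (−1.60, adjusted p = 0.0043) and ndhK of the plastid NADH dehydrogenase-like complex (−3.08, SE 0.63, adjusted p = 0.00794). The call of ndhK was lost without polysomal array 2 (adjusted p = 0.054), total array 1 (adjusted p = 0.0545) or total array 3 (adjusted p = 0.0537). The list median was −0.72 (camera adjusted p = 1.7e-12, but adjusted p = 0.94 with an estimated correlation).

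The cold comparison of polysomal with total RNA gave 645 calls, 132 higher and 513 lower on polysomes, against 606 (221 higher and 385 lower) after loess normalisation. Calls shared with non-stress numbered 42 higher and 143 lower (0.366 and 4.31 expected for independent lists). The count was 1142 with the replicate number as a block, 2726 without the CSP1-IP arrays, 3064 with array weights and 1117 with the compared groups alone. Leaving out an array gave 159 (polysomal array 3), 171 (total array 1), 209 (polysomal array 2), 252 (total array 3) or 307 (total array 2).

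The change of the polysomal against total RNA difference with cold was tested as a difference of differences in HF-RPL18. LTI30 had a value of −1.01 (SE 0.64, adjusted p = 1) and COR47 of −0.50 (SE 0.42, adjusted p = 1). The CBF regulon list as a whole lay lower, with a median of −0.50 (camera adjusted p = 0.0018, and adjusted p = 0.013 with an estimated correlation), although 0 of its 5 measured members passed, also when adjusted over the list alone. Its polysomal against total RNA median was 0.67 in non-stress (camera adjusted p = 0.0345, but adjusted p = 0.151 with an estimated correlation). In cold that median was −0.07 (camera adjusted p = 0.942). By these medians the lower value went with an excess on polysomes in non-stress rather than with a deficit in cold. That excess did not pass with an estimated correlation, so the source of the lower value is not settled. The plastid-encoded list had a median of −0.46 (camera adjusted p = 6.4e-10, but adjusted p = 0.68 with an estimated correlation). No probe set passed in limma, 123 had an unadjusted p below 0.05, and 2 passed with the replicate number as a block.

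The CSP1-IP arrays stood apart from the others in the GAPDH and ubiquitin control probe sets and in spread. The GAPDH 3′ control probe set exceeded the 5′ one by 6.90 (median, range 5.02 to 7.60) on CSP1-IP arrays, against medians of 1.29 on total and 1.47 on polysomal arrays. The actin 3′ minus 5′ difference did not stand apart, with a median of 3.53 (range 2.78 to 4.35) against 3.79 and 3.92. CSP1-IP values also spanned a narrower range, with SDs over probe sets of 1.83 to 2.14 against 2.22 to 2.32. Within groups they varied more. The SD of deviations from the group mean averaged 0.371, against 0.197 on total and 0.223 on polysomal arrays. The tests share a spread over all groups, which is on average too small for CSP1-IP arrays and too large for the others. The p-values of CSP1-IP comparisons therefore tend to be too small, and those of the others too large. The median of all probe sets in CSP1-IP minus total RNA was 0.13 and 0.20 in HF-RPL18 (non-stress and cold) and 0.20 and 0.16 in CSP1-FH. After loess normalisation of every array these medians were at most 0.01 from 0. List medians are therefore also given relative to all probe sets.

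**Figure D2:**
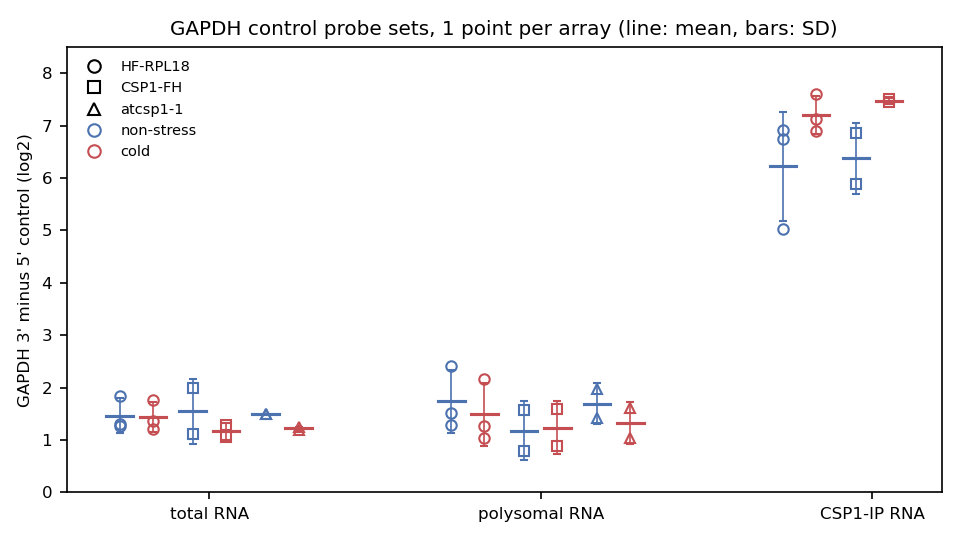
Difference between the 3′ and the 5′ GAPDH control probe sets (log2) on each array of the 3 RNA pools. Points are arrays, lines are group means and bars are SDs, with colours for the conditions and shapes for the lines. The CSP1-IP arrays lie between 5.02 and 7.60, above every total and polysomal array.

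CSP1-IP RNA was compared with total RNA of the same line and condition to find mRNAs recovered with CSP1. In non-stress HF-RPL18 many cytosolic ribosomal protein mRNAs were higher in CSP1-IP, among them AT2G40010 (RPP0A; 2.66, adjusted p = 1.74e-07), at 7.61 ± 0.22 against 4.94 ± 0.47 (n = 3 in each group), AT3G28500 (RPP2C; 2.57), AT5G02610 (RPL35D; 2.38) and AT2G19740 (RPL31A; 2.27). Of 120 measured members 68 were higher and 4 lower, and 71 and 5 were when adjusted over the list alone. The list median was 0.74, which was 0.62 above all probe sets (1.25 above after loess normalisation). The medians of random lists of the same level lay between −0.69 and −0.16. Camera gave an adjusted p of 1.1e-11 for this list, but adjusted p = 0.34 with an estimated correlation. The largest excesses among named genes were those of DI21, a drought-induced gene (4.66, adjusted p = 1.58e-08; 9.77 ± 0.95 against 5.12 ± 0.32), AT4G27654 (3.85), AT1G78480 (3.78) and AT2G35750 (3.66).

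Most plastid-encoded mRNAs were lower in the CSP1-IP of non-stress HF-RPL18. The largest deficit was that of ndhA (−6.77, SE 0.38, adjusted p = 1.53e-12), at 4.14 ± 1.14 against 10.90 ± 0.05, followed by petB (−5.06), cemA (−4.92), atpA (−4.90) and psbE (−4.89). Of 69 members 54 were lower and 0 higher, and 56 were lower when adjusted over the list alone. The median relative to all probe sets was −2.46 (−2.00 after loess normalisation), with camera adjusted p = 7e-26, but adjusted p = 0.15 with an estimated correlation. Among 8 measured nuclear genes of plastid ribosomal proteins 6 were lower, also when adjusted over the list alone (AT1G64510 −2.04, adjusted p = 3.81e-07). Their median was −1.30 (adjusted p = 0.15 with an estimated correlation), inside the range of −1.45 to 0.57 of random lists of the same level. Relative to all probe sets it was −1.43 (−0.76 after loess normalisation). Of 7 nuclear photosynthesis genes 4 were lower, also when adjusted over the list alone (ATPC1 −1.58, adjusted p = 6.65e-07), and after loess normalisation 2 were higher and 2 lower. The photosynthesis list lost its call with an estimated correlation (adjusted p = 0.215) and after loess normalisation (median −0.11, adjusted p = 0.545).

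In the remaining fixed lists of this comparison, the CBF regulon gene STZ was higher (2.50, adjusted p = 0.00141) and COR15B lower (−1.69, adjusted p = 0.00015), 1 each also when adjusted over the list alone. The guard cell gene FMA was lower (−1.04, adjusted p = 0.0022), a call lost against polysomal RNA (−0.57, adjusted p = 0.0888). The anthocyanin gene DFR was higher (2.61, adjusted p = 0.0298), a call lost without total array 2 (2.03, adjusted p = 0.143) or 3 (2.03, adjusted p = 0.145) or CSP1-IP array 2 (2.53, adjusted p = 0.0714) or 3 (2.42, adjusted p = 0.0809). Among 11 mitochondrion-encoded genes cox1 was lower (−2.34) and nad6 higher (0.79), 1 each also when adjusted over the list alone. The translation factor gene EIF4A-2 was at −0.68 (adjusted p = 0.0442), a call lost after loess normalisation (−0.14, adjusted p = 0.761). It was also lost without total array 1 (−0.52, adjusted p = 0.191) or 2 (−0.72, adjusted p = 0.0732) or CSP1-IP array 1 (−0.75, adjusted p = 0.0558), 2 (−0.64, adjusted p = 0.107) or 3 (−0.65, adjusted p = 0.0961). Its list had a median of −0.11 that turned to 0.44 after loess normalisation. Limma called 7226 probe sets, 3349 higher and 3877 lower in CSP1-IP.

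In cold HF-RPL18, 35 of 69 plastid-encoded mRNAs were again lower in CSP1-IP, with ndhA at −6.06 (adjusted p = 4.29e-12; 4.87 ± 0.60 against 10.93 ± 0.24, n = 3 in each group), psbE at −4.13 and petB at −4.03. None was higher, and the counts were the same when adjusted over the list alone. The median relative to all probe sets was −1.49 (−0.58 after loess normalisation), with camera adjusted p = 8.2e-08, but adjusted p = 0.42 with an estimated correlation. Against polysomal RNA the list median was −0.24, in place of −1.28 against total RNA, and turned to 0.02 after loess normalisation (camera adjusted p = 0.00977 as deposited, but adjusted p = 0.709 with an estimated correlation). Cytosolic ribosomal protein mRNAs were split, with 30 higher and 25 lower (29 and 24 when adjusted over the list alone). The lower ones included AT2G17360 (RPS4A; −3.12, adjusted p = 5.11e-08) and AT4G10450 (RPL9D; −2.40). The ribosomal protein median relative to all probe sets was −0.17 and turned to 0.74 after loess normalisation, which gave 62 higher and 7 lower members (camera adjusted p = 7.52e-12, but adjusted p = 0.513 with an estimated correlation). AT2G15880 had the largest excess (5.64, adjusted p = 4.04e-11; 8.91 ± 0.44 against 3.27 ± 0.57), followed by AT2G35750 (4.01) and AT1G69510 (3.57). The total RNA mean of AT2G15880 lay below the dim-filter level of log2 3.30, so the size of its excess is uncertain.

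Of 8 nuclear genes of plastid ribosomal proteins 7 were lower in the cold CSP1-IP of HF-RPL18, and 8 were when adjusted over the list alone (median −1.84, camera adjusted p = 9e-06, but adjusted p = 0.16 with an estimated correlation). In that comparison the CBF regulon median was −0.71 and turned to 0.09 after loess normalisation. Limma called 12672 probe sets, 7269 higher and 5403 lower. The count was 7078 after loess normalisation, 7201 with array weights, 7998 with the dim filter, 5851 with the compared groups alone and 7863 without CSP1-IP cold arrays 1 and 3, which had the narrowest ranges.

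In the non-stress CSP1-IP of CSP1-FH, a separate line, many cytosolic ribosomal protein mRNAs were again higher and many plastid-encoded ones lower. DI21 was higher by 4.71 (adjusted p = 4.05e-07), at 10.55 ± 0.66 against 5.84 ± 0.09 (n = 2 in each group), AT1G70270 and AT2G35750 were each higher by 4.16, and AT2G40010 was higher by 2.69 (adjusted p = 4.01e-06). The plastid-encoded genes ndhA (−7.31, adjusted p = 1.75e-11; 3.64 ± 0.13 against 10.95 ± 0.05), atpB (−6.23) and psbE (−5.50) were lower. Of 120 cytosolic ribosomal protein genes 53 were higher and 8 lower (56 and 10 when adjusted over the list alone), with a median 0.37 above all probe sets (1.36 after loess normalisation). That list passed at camera adjusted p = 2.1e-05, but adjusted p = 0.42 with an estimated correlation. Of 69 plastid-encoded genes 37 were lower (39 lower and 1 higher when adjusted over the list alone), with a median of −1.78 relative to all probe sets (−1.04 after loess normalisation; adjusted p = 0.24 with an estimated correlation). Against polysomal RNA the plastid-encoded median was −0.82 (−0.30 after loess normalisation; adjusted p = 0.416 with an estimated correlation), in place of −1.57 against total RNA.

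In cold CSP1-FH, AT2G15880 (4.3, adjusted p = 4.48e-07) and AT4G22160 (3.77) were the highest in CSP1-IP against total RNA, and ndhA (−5.58, adjusted p = 3.15e-09) and psbE (−4.45) the lowest. The total RNA mean of AT2G15880 (3.22) was again below the dim-filter level of log2 3.30. Of the cytosolic ribosomal protein genes 28 were higher and 9 lower (29 and 9 when adjusted over the list alone), with a median 0.21 above all probe sets (0.88 after loess normalisation; adjusted p = 0.69 with an estimated correlation). Of the plastid-encoded genes 24 were lower, and 27 were when adjusted over the list alone (median −1.09, adjusted p = 0.31 with an estimated correlation). The median was −1.83 on CSP1-IP array 1 and −0.43 on array 2. Against polysomal RNA the plastid-encoded median was −0.46 (−0.20 after loess normalisation; adjusted p = 0.538 with an estimated correlation), and the ribosomal protein list did not pass (median 0.31, camera adjusted p = 0.0955). Limma called 8222 probe sets in non-stress and 6267 in cold. Calls shared between HF-RPL18 and CSP1-FH numbered 1955 higher and 3070 lower in non-stress (635 and 666 expected for independent lists) and 2164 higher and 2915 lower in cold (986 and 756 expected). The CSP1-IP arrays of both lines also had a narrower value range and a larger GAPDH 3′ minus 5′ difference than the other pools. Whether these raised the overlap was not tested, so the overlap does not by itself show recovery with CSP1.

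The CSP1-FH counts depended on the fit. After loess normalisation the non-stress count was 5442, and with the compared groups alone the counts were 4006 in non-stress and 4065 in cold. Leaving out an array gave 5164 (total array 1), 5276 (total array 2) or 5409 (CSP1-IP array 2) in non-stress, and 3358 (total array 1) or 3604 (total array 2) in cold.

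**Figure D3:**
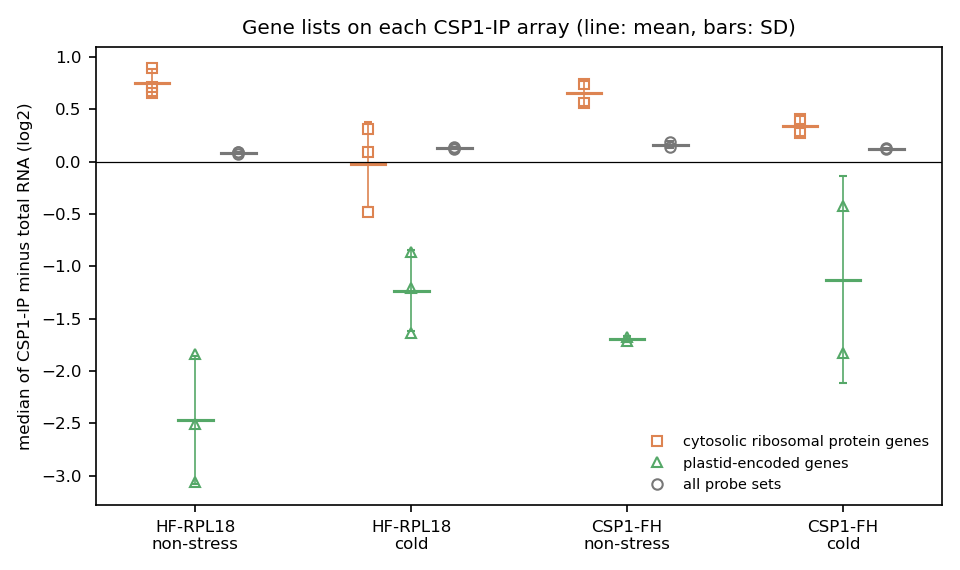
Median log2 difference between each CSP1-IP array and the mean of the total RNA group of the same line and condition, for cytosolic ribosomal protein genes (squares), plastid-encoded genes (triangles) and all probe sets (circles), as deposited. Points are arrays, lines are means and bars are SDs. Ribosomal protein medians lie above 0 on every array but HF-RPL18 cold array 3 (−0.48), and the group median of HF-RPL18 cold relative to all probe sets turned from −0.17 to 0.74 after loess normalisation, whereas plastid-encoded medians lie below 0 on all arrays.

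The change of the CSP1-IP against total RNA difference with cold was tested as a difference of differences in HF-RPL18. The largest increases were those of AT2G15880 (3.59, adjusted p = 0.000833) and AT2G34620 (2.47), and the largest decreases those of AT5G62280 (−4.00, adjusted p = 0.000677), AT5G20790 (−3.65, adjusted p = 0.000391) and the RNA helicase gene PRH75 (−3.27, adjusted p = 0.00425). The total RNA means of AT2G15880 (2.62 in non-stress and 3.27 in cold) were below the dim-filter level of log2 3.30. So was the non-stress total RNA mean of AT5G62280 (3.15). AT5G62280 and AT5G20790 were among the genes with the largest rises in total RNA in the cold. Of 120 cytosolic ribosomal protein genes 12 moved lower, led by AT2G17360 (−2.57, adjusted p = 0.00351), and 52 did when adjusted over the list alone. The list median was −0.87 (−0.62 after loess normalisation), with camera adjusted p = 8.2e-21, but adjusted p = 0.34 with an estimated correlation. Of 69 plastid-encoded genes 5 moved higher, also when adjusted over the list alone (psbF 1.75), with a median of 1.1 (adjusted p = 0.34 with an estimated correlation).

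The test of this change called 1020 probe sets in HF-RPL18, 447 higher and 573 lower, and 12 of 100 splits of these arrays, the real one included, gave as many. Splits can carry the difference between pools into this change, so that share does not measure chance. The number of calls was 401 after loess normalisation, 54 with array weights, 13 with the compared groups alone and 626 with the dim filter. Leaving out an array gave 478, 488 or 625 (total cold array 1, 2 or 3), 563 or 489 (total non-stress array 2 or 3), 1661 or 3363 (CSP1-IP cold array 1 or 2) and 670 (CSP1-IP non-stress array 3). In CSP1-FH 23 probe sets passed, led by AT5G20790 (−4.36, adjusted p = 0.0022), and the ribosomal protein list had a median of −0.31 (camera adjusted p = 0.00026, but adjusted p = 0.87 with an estimated correlation), and −0.51 after loess normalisation.

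Few probe sets passed in the test of CSP1-FH against HF-RPL18 in the CSP1-IP against total RNA difference, which with 2 against 3 arrays per group does not show that the lines are alike. In non-stress 6 probe sets passed, including AT1G54650 (1.71), AT2G25360 (1.4) and AT1G48690 (1.31), each with an adjusted p of 0.0451, and 4 of the 6 were higher. After loess normalisation 1 passed, which was lower. In cold 13 passed, 7 higher and 6 lower, including AT1G20580 (1.91, adjusted p = 0.00117) and AT3G59070 (−2.00, adjusted p = 0.00117). After loess normalisation 13 passed, 9 higher and 4 lower. No cytosolic ribosomal protein or plastid-encoded gene passed, also when adjusted over the list alone. The ribosomal protein median was 0.39 in cold (camera adjusted p = 1.25e-05, but adjusted p = 0.895 with an estimated correlation), and 0.18 after loess normalisation. The plastid-encoded median in non-stress was 0.42 (camera adjusted p = 0.0461, but adjusted p = 0.728 with an estimated correlation). The ribosomal protein median in non-stress was −0.13 and turned to 0.13 after loess normalisation (camera adjusted p = 0.0185 as deposited, but adjusted p = 0.728 with an estimated correlation).

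The lines were compared within each pool and condition to find mRNAs that depend on CSP1. The reference line carries a tagged ribosomal protein, and no wild-type arrays were analysed here. A trait of HF-RPL18 itself therefore cannot be told apart from an effect of CSP1 in the comparisons with that line. The targeted gene had no named probe set and was not checked by name. AT1G43590 was lower in non-stress atcsp1-1 than in HF-RPL18 in total RNA (−2.31, adjusted p = 0.0084; 2.98 ± 0.46, n = 2, against 5.29 ± 0.62, n = 3) and polysomal RNA (−2.38, adjusted p = 0.0054). The atcsp1-1 mean in total RNA lay below the dim-filter level of log2 3.30, so the size of that difference is uncertain. AT1G43590 was lower in CSP1-FH too, by 2.25 in total RNA (adjusted p = 0.0131) and 2.38 in polysomal RNA (adjusted p = 0.0051). The unnamed probe set 258900_at, chosen after its values were seen, was lower in atcsp1-1 in all 4 comparisons, at −2.07 (adjusted p = 7.14e-08) and −1.60 (adjusted p = 1.91e-05) in total RNA and −1.86 and −1.7 in polysomal RNA of non-stress and cold plants. It was lower in CSP1-FH in all 4 too, at −1.78 (adjusted p = 2.04e-06) and −1.64 (adjusted p = 1.2e-05) in total RNA and −1.91 (adjusted p = 4.43e-07) and −1.64 (adjusted p = 1.15e-05) in polysomal RNA of non-stress and cold plants.

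Among gene groups, the 120 cytosolic ribosomal protein genes of atcsp1-1 had a median of 0.31 in total RNA in the cold against HF-RPL18 (camera adjusted p = 7.7e-35, but adjusted p = 0.15 with an estimated correlation). In CSP1-FH that median was 0.32 (camera adjusted p = 1.4e-27, but adjusted p = 0.14 with an estimated correlation). The plastid-encoded genes of CSP1-FH lay lower in polysomal RNA in non-stress, with a median of −1.0 (camera adjusted p = 2e-49, and adjusted p = 0.028 with an estimated correlation). That list was not lower there alone. Its median was −0.60 in non-stress total RNA, −0.77 in cold total RNA and −0.56 in cold polysomal RNA. Each passed camera at its preset correlation, but not with an estimated correlation (adjusted p = 0.285, 0.144 and 0.27). No member of these lists passed in those comparisons, also when adjusted over the list alone. The mutant was also set against CSP1-FH, without HF-RPL18 arrays. There the CBF regulon list lay higher in non-stress total RNA of atcsp1-1, with a median of 0.36. It passed camera (adjusted p = 0.000678, and adjusted p = 0.00928 with an estimated correlation), although 0 of its 5 members did. In cold total RNA it did not pass (median −0.02, camera adjusted p = 0.976). A trait of CSP1-FH cannot be told apart from loss of CSP1 there.

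Counts of calls between lines were 2 in non-stress and 1 in cold, in total RNA and in polysomal RNA, for atcsp1-1 and for CSP1-FH, and each called probe set was lower than in HF-RPL18. For atcsp1-1 the numbers with an unadjusted p below 0.05 were 103 and 147 in total RNA and 161 and 348 in polysomal RNA (non-stress and cold). After loess normalisation 3 passed in non-stress polysomal RNA in each line, 1 higher and 2 lower. With the compared groups alone limma called 0 in all 8 comparisons. Same-numbered total and polysomal arrays of different lines deviated together, and with the replicate number as a block the cold polysomal count was 2 in each line. The calls of both lines are the same probe sets. Both lines were compared with the same HF-RPL18 arrays, so part of that overlap can come from these arrays or from a trait of the HF-RPL18 line. In 20 simulations of unchanged lines against the same arrays 0 calls were shared, but these gave at most 1 call in a comparison and so say little of the overlap. Across probe sets, which are not independent replicates, the differences of the 2 lines from HF-RPL18 had a correlation of 0.50 in total and 0.42 in polysomal RNA in non-stress. The simulations gave 0.47 and 0.44. In cold the correlations were 0.72 and 0.73, against 0.43 and 0.49 simulated. The covariances were 0.0193 and 0.0225 in non-stress (0.0273 and 0.0334 simulated) and 0.0370 and 0.0498 in cold (0.0214 and 0.0311 simulated). The shared deviations of same-numbered arrays of different lines can also raise such values. The excess over the simulations in cold therefore does not show a change common to both lines.

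The call of AT1G43590 in atcsp1-1 was lost in total RNA without HF-RPL18 array 2 (adjusted p = 0.0875) or 3 (adjusted p = 0.15) or atcsp1-1 array 1 (adjusted p = 0.954). In polysomal RNA it was lost without HF-RPL18 array 3 (adjusted p = 0.0652) or atcsp1-1 array 1 (adjusted p = 0.342) or 2 (adjusted p = 0.0587). In CSP1-FH the call of AT1G43590 was lost in total RNA without HF-RPL18 array 2 (adjusted p = 0.148) or 3 (adjusted p = 0.228) or CSP1-FH array 1 (adjusted p = 1) or 2 (adjusted p = 0.143). In polysomal RNA that was so without HF-RPL18 array 3 (adjusted p = 0.061) or CSP1-FH array 1 (adjusted p = 0.281) or 2 (adjusted p = 0.19). Without HF-RPL18 array 2, polysomal RNA in non-stress gave 4 calls in each line.

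To ask whether mRNAs recovered with CSP1 were loaded differently without it, the CSP1-IP set of CSP1-FH was followed in atcsp1-1 against HF-RPL18. In cold, polysomal relative to total RNA lay lower for the 1370 members than for the other probe sets (difference −0.0999, camera p = 0.00018, and p = 0.0269 with an estimated correlation). Of these members 68.3% lay below 0, against 52.9% of other probe sets. In non-stress the difference over 1936 members was −0.0347 (camera p = 0.132, and p = 0.36 with an estimated correlation). The 500 most enriched members gave −0.109 there and passed in camera at its preset correlation. No value with an estimated correlation is given for these members. Against random lists matched on level both conditions gave a permutation p of 1e-04, the smallest these lists can give, which leaves out the correlation between genes. Whether the shift differed between conditions was not tested. Limma called 0 members in either condition, with 2 (non-stress) and 6 (cold) at an unadjusted p below 0.05. The cold call was lost without HF-RPL18 polysomal array 3 (−0.0326) or atcsp1-1 polysomal array 1 (−0.0392). The non-stress difference passed without HF-RPL18 polysomal array 2 (−0.0630). The set was chosen on arrays of this series, and loss of CSP1 cannot be told apart from a trait of HF-RPL18 here either.

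No probe set passed in limma in the tests of whether lines differed in polysomal loading or in the cold response. For atcsp1-1 against HF-RPL18, 22 and 39 had an unadjusted p below 0.05 in polysomal against total RNA (non-stress and cold), and 61 and 134 in the cold response of total and polysomal RNA. For CSP1-FH against HF-RPL18 there were 46 and 68 in polysomal against total RNA. In simulations of atcsp1-1 against HF-RPL18, 0 of 200 probe sets changed by log2 1 and 142 of 200 changed by log2 2 were recovered in cold polysomal against total RNA, and 0 and 162 in the cold response of total RNA. These simulations left out the shared deviations of same-numbered arrays, so recovery in the data may differ.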

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

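The tests of the narrower value range, of cold in both lines, of shared HF-RPL18 arrays in the ribosomal protein cold response and of loss of CSP1 were chosen after the results were seen, as were loess normalisation (alone and with an estimated correlation), the random lists matched on level and the fit without HF-RPL18 CSP1-IP cold arrays 1 and 3. The differences of differences below passed the camera test at its preset correlation.

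Cytosolic ribosomal protein mRNAs lay above other probe sets in CSP1-IP against total RNA of non-stress HF-RPL18, with a list median of 0.74 (SE 0.19; adjusted p = 0.34 with an estimated correlation). A narrower value range of the CSP1-IP arrays would pull lists of that level together, but the highest bound of matched random lists was −0.164, below the list. A trend of the difference with probe-set level is argued against too, since the median was 1.25 (SE 0.16) after loess normalisation. Loss of 5′ ends stays open: over the 10 CSP1-IP arrays the list median and the GAPDH 3′ minus middle difference had a Pearson r of −0.308 (permutation p = 0.384), a Spearman rho of −0.152 (permutation p = 0.682), and an r of −0.476 without the 2 farthest arrays. Binding of CSP1 is a candidate explanation that stays open as well, because 0 CSP1-IP arrays of a line without CSP1 were analysed here.

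The same list lay lower in CSP1-IP against total RNA in cold than in non-stress in HF-RPL18, with a median of −0.870 (SE 0.27; adjusted p = 0.34 with an estimated correlation). Without the 2 arrays of narrowest value range the median was −0.707 (SE 0.22), and after loess normalisation it was −0.624 (SE 0.22), so neither the arrays nor a trend with level was excluded. In CSP1-FH the median was −0.314 (SE 0.33; camera adjusted p = 0.00026, but adjusted p = 0.87 with an estimated correlation), and −0.508 (SE 0.27) after loess normalisation. The value as deposited lies within 1 SE of 0, so an effect of cold in both lines stays open.

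The cold response of these mRNAs in total RNA lay higher in atcsp1-1 than in HF-RPL18, with a median of 0.465 (SE 0.29; adjusted p = 0.10 with an estimated correlation). For atcsp1-1 against CSP1-FH, which uses no HF-RPL18 arrays, the median was 0.209 (SE 0.32). Leaving out HF-RPL18 total non-stress array 1 gave 0.228, the lowest value with 1 HF-RPL18 array left out. CSP1-FH against HF-RPL18, where CSP1 is present, gave 0.247 (SE 0.29). In cold alone, the medians against HF-RPL18 were 0.31 in atcsp1-1 and 0.32 in CSP1-FH, and atcsp1-1 against CSP1-FH gave −0.02. The cold part of the difference was thus not particular to atcsp1-1. In non-stress, atcsp1-1 lay at −0.12 against HF-RPL18 and −0.21 against CSP1-FH. None of these medians passed with an estimated correlation. Shared arrays, a single array, a trait of the HF-RPL18 line and loss of CSP1 could each account for part of the difference, and these values do not decide between them.

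Other differences between groups that passed are given as values. In the cold change of polysomal against total RNA, the medians were −0.505 for the CBF regulon (adjusted p = 0.013 with an estimated correlation), −0.0561 for cytosolic ribosomal proteins (adjusted p = 0.89 with an estimated correlation), −0.463 for plastid-encoded genes (adjusted p = 0.68 with an estimated correlation) and 0.102 for UDP-glycosyltransferases (adjusted p = 0.035 with an estimated correlation). In the cold change of CSP1-IP against total RNA 1020 probe sets passed in limma, and the medians were −0.442 for nuclear-encoded plastid ribosomal proteins and 1.1 for plastid-encoded genes (adjusted p = 0.34 with an estimated correlation for each). The first of these was lost after loess normalisation (−0.21, adjusted p = 0.389).

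In atcsp1-1 against HF-RPL18, polysomal against total RNA had a median of −0.499 for plastid-encoded genes in non-stress (adjusted p = 0.76 with an estimated correlation) and −0.109 for cytosolic ribosomal proteins in cold (adjusted p = 0.82 with an estimated correlation). The latter passed in 4 of the 10 fits with 1 array left out, between −0.23 without HF-RPL18 total cold array 1 and −0.02 without atcsp1-1 polysomal cold array 1. In CSP1-FH against HF-RPL18 the non-stress value for plastid-encoded genes was −0.374 (adjusted p = 0.99 with an estimated correlation). The cold response of plastid-encoded genes in atcsp1-1 against HF-RPL18 had a median of −0.206 in total RNA (adjusted p = 0.71 with an estimated correlation), between −0.61 and 0.02 without atcsp1-1 total cold array 2 or 1, and of 0.354 in polysomal RNA (adjusted p = 0.68 with an estimated correlation). For cytosolic ribosomal proteins the polysomal value was 0.374 (adjusted p = 0.31 with an estimated correlation).

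GAPDH and ubiquitin control probe sets, outside the comparisons, stood apart on the CSP1-IP arrays. The GAPDH 3′ minus 5′ difference had a median of 6.90 there (total 1.29, polysomal 1.47), and that of ubiquitin was 2.88 (total 1.47, polysomal 1.4). That of actin did not stand apart (3.53, against 3.79 and 3.92).

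Other splits of the arrays of HF-RPL18 were counted for the comparisons of 3 against 3. In each, 1 of 10 splits, the real one, gave as many calls, and 10 splits are too few for a share under 0.05. The real counts were 2447 (cold, total), 2061 (cold, polysomal), 254 and 645 (polysomal against total, non-stress and cold), 7226 and 12672 (CSP1-IP against total, non-stress and cold). The highest other counts were 0, 0, 1, 0, 0 and 130. The splits that part all 3 numbers, as the real one does, called 0 in the 3 other cases for total and polysomal RNA. For the cold change of polysomal against total RNA (0 calls in limma, 123 at an unadjusted p below 0.05), 100 of 100 splits gave as many, which a real count of 0 fixes whatever the data, and the highest other count was 4106. For that of CSP1-IP against total RNA (1020 calls), 12 of 100 gave as many, with a highest other count of 7211. Splits can carry the difference between pools into this change, so that share does not measure chance, which was not excluded. A split that calls several times the real count points to a structure of the samples, whose nature was not tested.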

How the results depend on the processing

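The fits without the CSP1-IP arrays, with loess normalisation (alone or with an estimated correlation) and without HF-RPL18 CSP1-IP cold arrays 1 and 3, the matched lists and the check of numbers between lines were chosen after the data were seen. Of 2034 values of named genes under alternatives chosen before, 1850 kept their side of the threshold and 184 did not pass. Of 2114 with 1 array left out, 1735 kept it and 379 did not pass. Of 563 under added ones, 463 kept it, 98 did not pass and 2 reversed. The CSP1-IP arrays varied more within groups than the others (mean SD of deviations 0.371, against 0.197 on total and 0.223 on polysomal arrays). The shared spread therefore tends to raise counts of CSP1-IP comparisons and to lower the others. Other causes were not tested except where fewer arrays or probe sets were used. Sequence features were not run. Arrays per group limit what can be seen.

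Counts below follow the order total cold response, polysomal cold response, polysomal against total RNA in non-stress and in cold (HF-RPL18). With array weights they were 4806, 3565, 1217 and 3064, and without the CSP1-IP arrays 3970, 3680, 1363 and 2726. With the compared groups alone the last pair was 95 and 1117. For CSP1-IP against total RNA in cold HF-RPL18 the count was 7201 (array weights), 5851 (compared groups alone), 7998 (dim filter), 7078 (loess) or 7863 (without CSP1-IP cold arrays 1 and 3). In CSP1-FH it was 5442 (loess) or 4006 (compared groups alone) in non-stress and 4065 (compared groups alone) in cold. The cold change of CSP1-IP against total RNA gave 54 (array weights), 13 (compared groups alone), 626 (dim filter) and 401 (loess).

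With the replicate number as a block, which pairs total and polysomal arrays of HF-RPL18, polysomal against total RNA gave 500 and 1142 calls and its cold change 2. Same-numbered arrays of different lines correlated in their deviations at 0.15 to 0.58 in non-stress and 0.20 to 0.55 in cold (total or polysomal RNA, 12 pairs each), and at 0.07 to 0.15 for CSP1-IP. Lines share 2 numbers, too few to settle the pairing. Where pairing was not shown, the block gave 1619 for the cold change of CSP1-IP against total RNA and 2 each in cold polysomal RNA of atcsp1-1 and CSP1-FH against HF-RPL18. It changed no call of the 364 named genes. Of 192 list results 6 lost their call under the block, 3 gained one and 1 reversed. The ribosomal protein median in CSP1-FH against HF-RPL18 (total, non-stress) turned to −0.034 under the block.

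Against HF-RPL18, in total RNA (non-stress, cold) and polysomal RNA (non-stress, cold), array weights gave 4, 3, 4 and 4 for atcsp1-1 and 5, 6, 5 and 5 for CSP1-FH, and the compared groups alone gave 0 in all 8. Without the CSP1-IP arrays atcsp1-1 had 4, 2, 4 and 2, and CSP1-FH had 2 in cold total, 6 in non-stress polysomal and 5 in cold polysomal RNA. The trended and robust prior gave 2 in cold polysomal RNA of atcsp1-1. Loess gave 3 in non-stress polysomal RNA of each line.

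Leaving out 1 array gave 27 to 184 and 159 to 649 for polysomal against total RNA (non-stress, cold), 5164 to 7920 and 3358 to 5057 for CSP1-IP in CSP1-FH, and 478 to 3363 for the cold change of CSP1-IP. Non-stress counts against HF-RPL18 were 1 to 2 in total and 1 to 4 in polysomal RNA for each line. The CSP1-IP set difference in polysomal against total RNA of atcsp1-1 was −0.0630 to −0.00854 in non-stress and −0.139 to −0.0326 in cold. In non-stress it was −0.109 for the 500 most enriched and −0.0357 with matched lists. Over 24 comparisons, which among others leave out the cold responses within atcsp1-1 and CSP1-FH, passing pairs with a fixed list were 58, with 54 to 71 when 1 array was left out, 4 with an estimated correlation and 3 with that and loess. Against polysomal RNA 31 of 32 list results in CSP1-IP comparisons kept their side of the threshold. Named genes reversed were COR47 in cold CSP1-IP against total RNA of HF-RPL18 (0.090 under loess) and CML38 there (−0.40 without CSP1-IP cold arrays 1 and 3).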

Other observations

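Members of gene groups chosen after the names in the annotation had been seen also passed in the cold response of total RNA of HF-RPL18. Of 11 late embryogenesis and dehydration genes 4 rose, led by COR27 (3.11) and DI21 (2.04), and 5 did when adjusted over the list alone (camera adjusted p = 0.00292, and adjusted p = 0.00871 with an estimated correlation). Of 27 expansins and xyloglucan hydrolases 3 rose and 5 fell (3 and 6 when adjusted over the list alone), from EXLA1 (4.05) to EXPB3 (−1.79). Of 47 UDP-glycosyltransferases 7 rose and 4 fell (9 and 4 when adjusted over the list alone), including UGT72B3 (2.72) and UGT74B1 (−1.96). Of 14 SWEET transporters 2 rose and of 7 tubulins 1 rose and 2 fell. Of 13 early stress genes 4 rose and 1 fell, and of 19 further nuclear chloroplast genes 3 fell (NdhN −1.15). None of these other lists passed as a whole.

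On polysomes in cold HF-RPL18, UDP-glycosyltransferases lay higher than in total RNA, with a median of 0.19 over 47 genes (camera adjusted p = 0.0013, and adjusted p = 0.030 with an estimated correlation). UGT72E1 (1.34, adjusted p = 0.00618) and UGT71C2 (0.86, adjusted p = 0.00554) were higher. In non-stress CSP1-IP against total RNA of that line, the early stress genes WRKY53 (2.59, adjusted p = 1.56e-05) and STZ (2.50, adjusted p = 0.00141) were higher, and 14 of 19 further nuclear chloroplast genes were lower.

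The clock gene GI had values of 6.28 to 6.64 on the non-stress total and polysomal arrays numbered 2 of all 3 lines, and 3.31 to 3.89 on the other non-stress arrays of those pools. The non-stress CSP1-IP array numbered 2 of HF-RPL18 had 6.24, against 3.94 and 4.31 on the others, and those of CSP1-FH had 5.18 and 5.08. The labels do not say whether a number marks a harvest shared by the lines, so a shared harvest stays open for these values and for the tests between lines, which were run without a block. The rise of GI in the cold in total RNA of HF-RPL18 was 4.87 with and without the block. Both groups hold the same numbers, so the block could not change that value.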
